A study of Homo sapiens with 54 samples.

How the data were processed

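The series holds 54 poly(A) RNA sequencing libraries in 18 groups of 3 from HEK293T cells, a human embryonic kidney line, and THP-1 cells, a human monocytic leukaemia line. Per the labels' protocols, the libraries were made with a stranded mRNA kit and sequenced as read pairs on a NovaSeq X Plus instrument. The labels place 42 libraries (14 groups) on lanes of the 10B type and 12 libraries (4 groups) on lanes of the 25B type. The 12 libraries are siControl, siPOLR3A, HEK293T DMSO and HEK293T ML60218. Each comparison within a cell line lies on a single lane type. The labels do not say whether replicates were grown and treated independently.

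The submitters' processing notes name bcl2fastq 2.20, Trim Galore, Salmon and DESeq2 and the genome build hg38. What each tool was used for and the versions of the last 3 are not given in the sources used here. Per the file headers, the deposited table gives for each transcript and library an estimated count of read pairs under the name Salmon gives its counts, which is not normalised. Not all of these estimated counts are whole numbers. The authors also deposited TPM values (scaled by transcript length and library total) for the same 54 libraries. The TPM values served here only to derive average transcript lengths for an alternative fit. All 54 columns of estimated counts and all 54 of TPM were used.

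The table holds 194142 transcripts. Of these, 158359 were matched to a gene through GENCODE release 29 and 10510 through a table of gene symbols, and 25273 (13.0%) had no match. Matched transcripts carried between 92.75% and 93.86% of each library's estimated counts. The annotation release behind the deposited table is not given in the sources used here, so identifiers that changed between releases were left out. Summing per gene and rounding gave 35053 genes, of which 31469 had at least 1 read. Read sharing between near-identical copies or overlapping genes was decided by Salmon, so the levels of histone genes, the PSG family, HSPA1A and HSPA1B, TMEFF1 (which a read-through transcript overlaps), HIST2H2AA3 and similar genes are uncertain. Only poly(A) RNA was measured, so the levels of histone genes here need not follow their total RNA. The strand setting of the quantification is not given in the sources used here, so genes with an antisense partner carry the same limit.

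Library totals ran from 83.5 to 131.3 M estimated read pairs. Within groups, replicate pairs varied more than counting error alone would give (chi-square per degree of freedom from 4.331 to 63.85). The biological coefficient of variation fitted per comparison ran from 3.52% to 6.48%. Levels are CPM (counts relative to the library total), with totals scaled by the trimmed mean of M values (TMM), given as mean ± SD of 3 libraries.

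Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr (minimum count 10, minimum total 15). The test was edgeR's robust quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05, and every adjusted p for a gene comes from it. The standard error (SE) of a log2 fold change is its size divided by the square root of F. The prior count was 2. POLR3A siRNA, HEK293T ML60218, POLR3G siRNA, the POLR3G antisense oligonucleotide (ASO) and MAF1 were each fitted with their own 6 libraries. The 12 POLR3GL libraries shared a fit and a control group, and the 12 THP-1 libraries shared a fit. Differences between effects were tested as contrasts in fits of 12 libraries.

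Genes named in the text followed a rule fixed before the data were examined. It takes the targeted gene and its paralog, then the 8 largest rises and the 8 largest falls among protein-coding genes past the threshold. Those genes need a mean of at least 5 CPM in the higher group and no overlap between treated and control libraries, a separation that chance gives 3 against 3 libraries in 10% of genes. For differences between effects it takes the 6 largest each way without the overlap condition, and for the overlap of experiments the 10 genes per direction called in most of them. From each gene list it takes up to 4 members past the threshold, by smallest p. Whether a gene codes for protein was read from GENCODE. Some genes that this rule takes are not reported here, so the rankings in the text have gaps.

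Before the data were examined, 39 gene lists were also fixed. Lists with at least 3 measured members were tested with camera in limma 3.58.1 on log2 CPM, with a preset correlation of 0.01 between genes and adjustment over the lists of a comparison. The test was repeated with the correlation estimated from the residuals. The counts of members that rose or fell use the adjustment over all genes, and a second count is adjusted over the list alone. The list of Pol III transcripts had too few measured members and was not analysed here. The lists, and sets of called genes in other experiments, were also tested with fry.

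Whether replicate numbers pair the libraries was checked by correlating deviations from group means. Only CHX with CHX plus ML60218 gave same-number correlations all above those of other numbers (0.12 to 0.28, against at most 0.1). Fitting the replicate number as a block is an alternative for every comparison.

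The edgeR steps were tested on counts simulated from the fitted levels and spreads. In these, 200 genes were changed, as many raised as lowered, which is far fewer than passed in most comparisons. Across 11 comparisons, the share of false calls was 3.3% to 6.5% with a trended spread and 4.7% to 12.7% with gene-specific spreads. In the simulation of POLR3A siRNA with gene-specific spreads, 36 of 50 genes changed by 1.2-fold, 44 by 1.5-fold, 48 by 2-fold and 50 by 4-fold were recovered.

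Alternatives fixed beforehand were RLE factors, library size only, no low-count filter, protein-coding genes only, DESeq2 1.42.0, limma voom, the replicate block, only the 2 groups of a comparison, and leaving out each library in turn. Alternatives added after seeing the data were an offset for average transcript length, protein-coding genes only for the named genes, and library size only and the replicate block for the overlap of experiments and of POLR3GL siRNAs. Other splits of the libraries into groups of the same sizes were counted for each comparison. Matching and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and the R package data.table, in version 1.17.8.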

Results

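Poly(A) RNA was sequenced from 54 libraries of cultured human cells in 18 groups of 3. The groups change RNA polymerase III (Pol III), the enzyme that makes transfer RNAs and other short non-coding RNAs. HEK293T cells received siRNA against the subunit POLR3A for 2 days, siRNA or an antisense oligonucleotide (ASO) against POLR3G at 200 nM for 48 h, or 1 of 3 siRNAs against its paralog POLR3GL (siE4, siE6 and siE8, 25 nM, 48 h). Other HEK293T groups overexpressed the Pol III repressor MAF1 for 48 h or received the Pol III inhibitor ML60218 at 25 µM, for a time the labels do not give. THP-1 cells received ML60218 (25 µM, 4 h), cycloheximide (CHX, an inhibitor of translation, 10 µg/ml, 4.5 h), both, or DMSO. Totals per library ran from 83.5 to 131.3 M estimated read pairs. The comparisons ask how messenger RNAs differ when Pol III or its regulators are altered. Intervals and errors cover the libraries measured, and the labels do not say whether replicates are independent cultures.

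Marker sets fixed beforehand matched the cell line named for each group. The 12 HEK293T markers had a median of 29.7 to 55.1 CPM in the HEK293T groups and at most 0.168 CPM in THP-1 groups. The 12 THP-1 markers had a median of 153 to 181 CPM in THP-1 groups and at most 0.5 CPM in HEK293T groups. That highest value came from the POLR3G ASO libraries, where CD68, a macrophage marker, stood at 19.6 CPM against 3.07 CPM in the scramble ASO libraries. Fibroblast markers had medians of 1.66 to 6.21 CPM in HEK293T groups, with COL1A1 highest, and at most 0.0979 CPM in THP-1 groups.

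Each targeted gene moved in the direction its label names, in all 3 libraries. POLR3A (ENSG00000148606, hg38 chromosome 10, 77969251 to 78029545) stood at 13.9 ± 1.5 CPM with its siRNA, range 12.3 to 15, against 90.9 ± 1.1 CPM, range 89.7 to 91.7 (SD, n = 3), a log2 change of -2.71 (SE 0.068). POLR3G (ENSG00000113356, chromosome 5, 90471748 to 90514553) stood at 11.2 ± 2.3 CPM with siRNA, range 8.63 to 13.2, against 30.7 ± 3.4 CPM, range 28.7 to 34.6 (log2 -1.46, SE 0.19). With the ASO it stood at 9.74 ± 1.2 CPM, range 8.34 to 10.6, against 23.4 ± 1.9 CPM, range 21.4 to 24.9 (log2 -1.27, SE 0.11). POLR3GL (ENSG00000121851, chromosome 1, 145964702 to 145978848) stood at 32.8 ± 1.7 CPM in the control, range 31.4 to 34.6. Its log2 change was -3.54 with siE4 (range 2.68 to 2.96 CPM), -3.34 with siE6 (3.04 to 3.5 CPM) and -3.70 with siE8 (1.93 to 2.85 CPM). MAF1 (ENSG00000179632, chromosome 8, 144104499 to 144107611) stood at 2990 ± 200 CPM with its plasmid, range 2820 to 3200, against 41.6 ± 0.85 CPM, range 40.6 to 42.2 (log2 6.17, SE 0.055). In THP-1 cells POLR3G was close to absent, with a mean of 1.08 CPM in DMSO, where POLR3GL stood at 49.9 CPM.

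**Figure D1:**
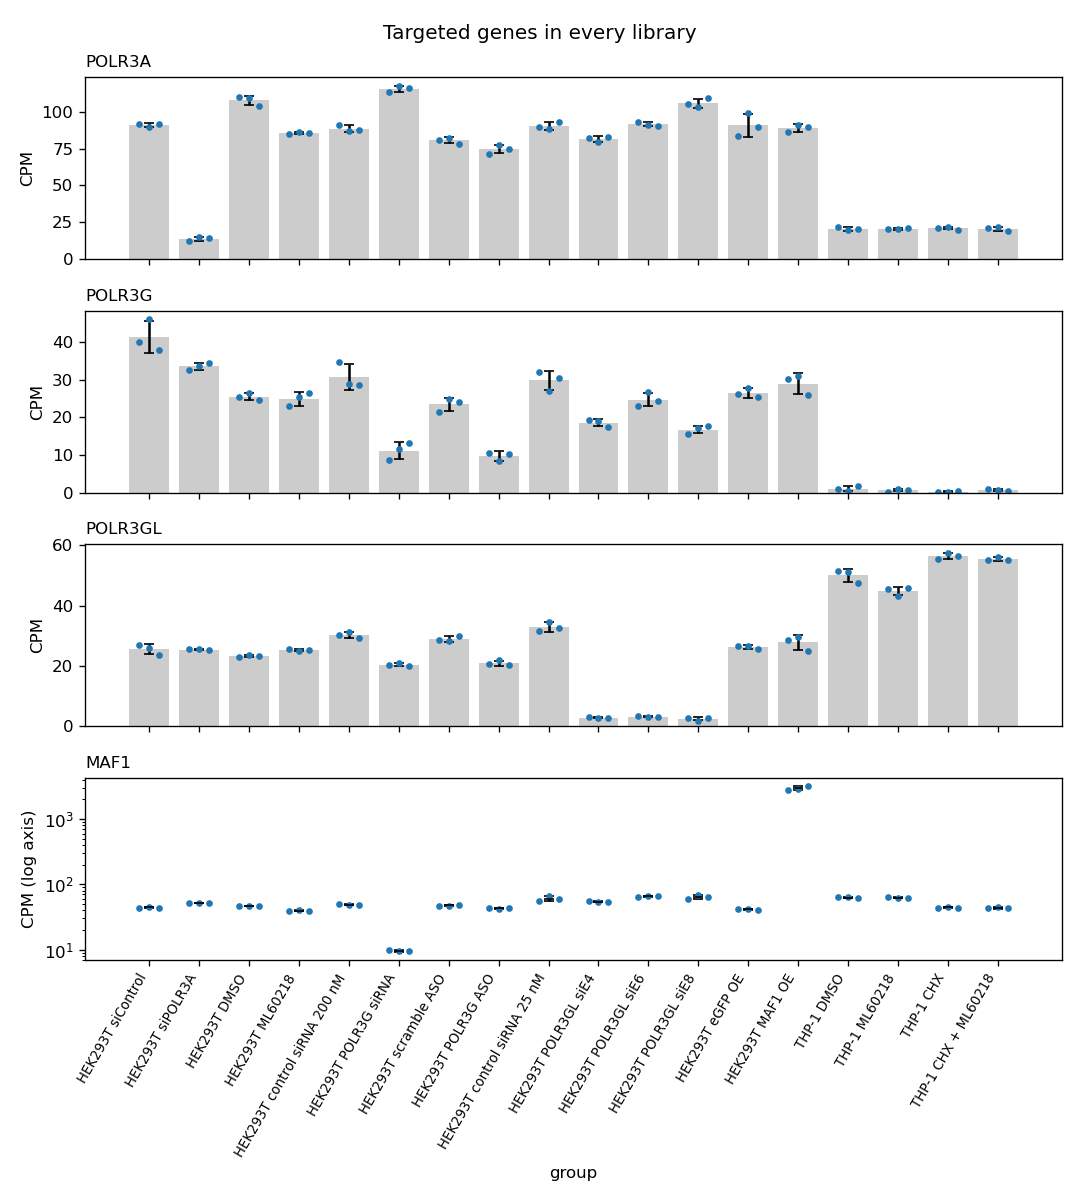
Levels of the targeted genes in TMM-scaled CPM in all 18 groups. Bars are means, error bars SDs of 3 libraries and points single libraries, and MAF1 is drawn as points on a log axis. For the gene that a treatment targets, no treated library overlaps its controls. This runs from POLR3A at 12.3 to 15 CPM against 89.7 to 91.7 CPM to MAF1 at 2820 to 3200 CPM against 40.6 to 42.2 CPM.

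**Figure D2:**
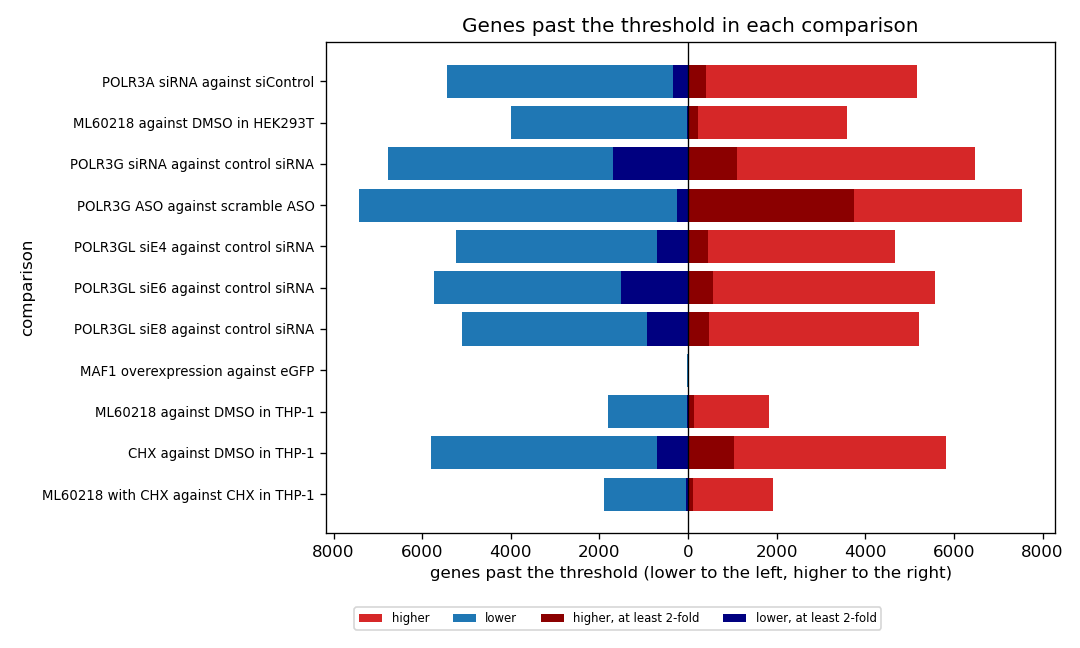
Numbers of genes past an adjusted p of 0.05 in each comparison (edgeR), lower genes to the left and higher genes to the right. Darker parts mark changes of at least 2-fold. Counts run from 40 genes with MAF1 to 14957 with the POLR3G ASO, where 3740 genes rose and 242 fell at least 2-fold.

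With POLR3A siRNA the synaptic vesicle protein SYP led the rises. It stood at 36.6 ± 0.72 CPM against 8.04 ± 0.6 CPM (log2 2.19, SE 0.047, n = 3 against 3). Next came the potassium channel KCNC1 (2.14, SE 0.069), the scaffold MAPK8IP2 (1.97), the lysosomal amino acid transporter SLC36A1 (1.85), the axon guidance factor NTN1 (1.80), the receptor KIT (1.68), MAPK11 (1.57) and CPLX1, which acts in neurotransmitter release (1.52). The mitochondrial protease PITRM1 fell further than the target itself, from 138 ± 3.6 to 9.42 ± 0.93 CPM (log2 -3.87, SE 0.058). POLR3A was followed by TCEAL3 (-2.48), NIBAN1 (-2.45), TCEAL4 (-2.40), TXNDC12 (-2.09), CDC123 (-2.06) and the lactate transporter SLC16A1 (-2.06). MAF1 was higher (log2 0.24, SE 0.026) and POLR3GL did not pass (log2 0.00, SE 0.044).

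With POLR3A siRNA, camera called 4 of the gene lists, 2 higher and 2 lower. Of 76 mitochondrial ribosomal proteins, 45 fell, 12 rose and 19 did not pass (45 and 13 adjusted over the list alone), among them MRPL19 (-1.02), MRPL20 (-0.89) and MRPS9 (-0.70). The adjusted p was 0.014, 0.99 with an estimated correlation and 0.051 without siControl replicate 3. Of 75 nuclear genes of oxidative phosphorylation, 42 fell, 9 rose and 24 did not pass, the same numbers adjusted over the list alone, with NDUFB10 (-1.5) and SDHC (-0.48) as examples (adjusted p = 0.014, and adjusted p = 0.99 with an estimated correlation). Zinc finger genes with ZNF symbols rose in 213 cases and fell in 84 of 454 (214 and 85 adjusted over the list alone), such as ZNF121 (0.91) and, lower, ZNF146 (-0.80), at an adjusted p of 0.013 (adjusted p = 0.99 with an estimated correlation). Of 22 NF-kB and inflammatory genes, 15 rose, 1 fell and 6 did not pass, equally so over the list alone, led by NFKB1 (0.48), CXCL2 (1.80) and TNFAIP3 (0.54). That list's adjusted p was 0.032, 0.99 with an estimated correlation and 0.10 without siPOLR3A replicate 1. In all, 10604 of 17118 genes passed, 5167 higher and 5437 lower, and 403 rose and 329 fell at least 2-fold. By library size only 6316 were higher and 4454 lower, and 20 mitochondrial ribosomal proteins rose and 37 fell, and 16 oxidative phosphorylation genes rose and 27 fell.

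In HEK293T cells, the largest rise with ML60218 was in CHAC1. This gene, for an enzyme of glutathione breakdown that ATF4 induces, stood at 15.1 ± 1 CPM against 1.84 ± 0.23 CPM in DMSO (log2 3.04, SE 0.096, n = 3 against 3). The histone gene H4C14 (2.30, SE 0.49) was next, then the stress-induced factors ATF3 (2.25, SE 0.23) and DDIT3 (2.06, SE 0.092), the peptide hormone ADM2 (1.89), ARRDC3 (1.88), H4C15 (1.83) and the phosphatase DUSP1 (1.82). H4C14, H4C15 and DUSP1 lost significance without any single DMSO library, at log2 2.33, 1.81 and 1.82 without replicate 1, 2.21, 1.84 and 1.80 without replicate 2, and 2.34, 1.85 and 1.83 without replicate 3. Largest falls were in the heat shock protein HSPA2 (-1.37, SE 0.17), the decoy receptor TNFRSF10D (-1.2), HSPA8 (-1.17), its partner DNAJB1 (-1.12), AMD1 of polyamine synthesis (-0.98), P2RY11 (-0.96), CBX6 (-0.92) and FASTKD5 (-0.92). POLR3A itself was lower (log2 -0.33, SE 0.032), as was MAF1 (-0.25, SE 0.034).

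Camera called 21 lists with ML60218 in HEK293T cells, 4 higher and 17 lower. Of 35 genes of the ATF4 and integrated stress response, 32 rose, 1 fell and 2 did not pass (33 and 1 adjusted over the list alone), led by CHAC1, STC2 (1.56), DDIT4 (1.5) and ASNS (1.00), at an adjusted p of 1.9e-17 (adjusted p = 0.46 with an estimated correlation). Of 75 nuclear genes of oxidative phosphorylation, 67 fell and 8 did not pass (68 fell adjusted over the list alone), among them SDHD (-0.35) and ATP5MC3 (-0.49), at 4.1e-14 (adjusted p = 0.52 with an estimated correlation). Mitochondrial ribosomal proteins fell in 56 of 76 cases with 20 not passing (56 lower and 1 higher adjusted over the list alone), such as MRPS17 (-0.50), at 4e-11 (adjusted p = 0.46 with an estimated correlation). Of 81 cytosolic ribosomal proteins 57 fell and 24 did not pass (67 fell adjusted over the list alone), RPS26 (-0.47) and RPL35A (-0.29) among them, at 1.2e-10 (adjusted p = 0.54 with an estimated correlation). Zinc finger genes rose in 222 of 456 cases and fell in 33 (232 and 34 adjusted over the list alone), led by ZNF711 (0.73), at 1.2e-09 (adjusted p = 0.52 with an estimated correlation). Of 36 G2/M genes 28 fell and 8 did not pass (28 fell and 2 rose adjusted over the list alone), with ANLN (-0.38) and AURKA (-0.58), at 3e-09 (adjusted p = 0.46 with an estimated correlation). Heat shock genes fell in 14 of 19 cases with 5 not passing (17 fell adjusted over the list alone), among them DNAJA1 (-0.55) and BAG3 (-0.48), at 8.8e-07 (adjusted p = 0.46 with an estimated correlation). Translation factors fell in 19 and rose in 5 of 44 cases (20 and 5 adjusted over the list alone; adjusted p = 0.0082, and 0.73 with an estimated correlation), but 8 fell and 10 rose when scaled by library size only. In all, 7582 of 17111 genes passed, 3596 higher and 3986 lower, against 5040 higher and 2381 lower by library size only. With that scaling 21 cytosolic ribosomal proteins fell and 2 rose (median -0.07 in place of -0.14), 9 heat shock genes fell, and 22 G2/M genes fell and 3 rose.

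With POLR3G siRNA the largest rise was in SCG3, which sorts granule cargo. It stood at 21.6 ± 1 CPM against 0.2 ± 0.061 CPM (log2 6.74, SE 0.1, n = 3 against 3). CPLX2 (6.64, SE 0.16), the granins CHGB (4.76) and CHGA (4.46), the vesicle priming factor UNC13A (4.39), the receptor GPR158 (3.99), AP3B2 of the neuronal adaptor complex (3.97) and RAB3C (3.83) followed. Largest falls were in CHAC1, from 22.3 ± 0.4 to 1.07 ± 0.058 CPM (log2 -4.38, SE 0.057), INHBE, a subunit of activin E (-3.91), and TXLNB (-3.71). The CHAC1 level in this control lay above that in HEK293T DMSO given above, across separate fits and lane types. How far the control level carries this fall was not tested. The Pol III repressor MAF1 was also lower, at 9.63 CPM against 49 CPM (log2 -2.35, SE 0.033), and fell further than POLR3G itself. With the ASO MAF1 stood at 42.9 CPM against 47.5 CPM. POLR3GL was lower with the siRNA as well (-0.56, SE 0.033), while POLR3A was higher (0.38, SE 0.023).

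Camera called 16 lists with POLR3G siRNA, 13 higher and 3 lower. Of 56 ribosome biogenesis factors, 52 rose, 3 fell and 1 did not pass, the same adjusted over the list alone, led by DDX10 (1.68), UTP14A (1.23), DDX52 (1.00) and UTP15 (1.15), at an adjusted p of 3.1e-12 (adjusted p = 0.5 with an estimated correlation). Of the 35 ATF4 and integrated stress response genes, 34 fell and 1 did not pass, again the same over the list alone, with the cystine transporter SLC7A11 (-2.70), PSAT1 of serine synthesis (-1.92), CHAC1 and ALDH1L2 (-2.16), at 1.8e-11 (adjusted p = 0.5 with an estimated correlation). MYC targets rose in 24 of 26 cases with 2 not passing, equally over the list alone, among them MRTO4 (1.03) and MYC itself (0.77), at 4.9e-07 (adjusted p = 0.5 with an estimated correlation). Of 75 oxidative phosphorylation genes 59 rose, 8 fell and 8 did not pass, unchanged over the list alone, with NDUFS1 (-1.5) and ATP5F1C (0.57), at 4.2e-06 (adjusted p = 0.52 with an estimated correlation). Heat shock genes rose in 16 and fell in 3 of 19 cases, the same adjusted over the list alone, led by HSPA1B (2.16) and DNAJA1 (1.74), at 0.00054 (adjusted p = 0.5 with an estimated correlation). Genes of cholesterol synthesis fell in 18, rose in 2 and did not pass in 3 of 23 cases, alike over the list alone, led by the regulator SREBF2 (-1.13), at 0.00058 (adjusted p = 0.5 with an estimated correlation). Pol III subunits rose in 14 and fell in 4 of 18 cases, unchanged over the list alone, with POLR3E lower (-1.15), at 0.0061 (adjusted p = 0.5 with an estimated correlation). In all, 13231 of 17115 genes passed, 6464 higher and 6767 lower, against 5305 and 7962 by library size only, where the median of all genes lay at -0.13.

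With the POLR3G ASO the largest rise was in a gene close to absent in its control. PSG5, a pregnancy-specific glycoprotein, stood at 13.7 ± 1.1 CPM against 0.151 ± 0.082 CPM (log2 6.49, SE 0.19, n = 3 against 3). TRARG1 (5.96), the mucin MUC4 (4.79), HSF5 (4.67), the integrin ITGAM (4.42), SPACA4 (4.23), AGBL2 (4.17) and PSG4 (4.17) came next. The leading fall, in the histone methyltransferase KMT2D (-3.16, SE 0.27), turned to log2 0.11 when transcript length was included as an offset. STUM followed at -2.59 (SE 0.053). ITGAM is also a marker of THP-1 cells, and CD68 stood at 19.6 CPM in these libraries, as given above. POLR3GL was lower as well (log2 -0.47, SE 0.041).

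Camera called 16 lists with the ASO, 6 higher and 10 lower. Of 81 cytosolic ribosomal proteins, 72 fell, 3 rose and 6 did not pass, the same adjusted over the list alone, by small amounts such as -0.50 for RPL3 and -0.28 for RPL7A, at an adjusted p of 2.7e-09 (adjusted p = 0.39 with an estimated correlation). Poly(A) RNA of replication-dependent histones rose in 51, fell in 2 and did not pass in 3 of 56 cases (52 and 2 adjusted over the list alone), led by H2BC6 (2.78), H3C6 (1.77), H4C15 (1.72) and H2AC6 (1.92), at 9.1e-09 (adjusted p = 0.3 with an estimated correlation). Of 75 oxidative phosphorylation genes 61 fell, 2 rose and 12 did not pass, unchanged over the list alone, with NDUFA10 (-0.49) first, at 1.2e-07 (adjusted p = 0.39 with an estimated correlation). Immediate early genes rose in 29, fell in 2 and did not pass in 4 of 35 cases, alike over the list alone, led by DUSP1 (1.28), KLF6 (0.94) and ATF3 (0.85), at 1.1e-05 (adjusted p = 0.3 with an estimated correlation). All 13 mitochondrially encoded mRNAs fell, also over the list alone, such as MT-CYB (-0.51), at 4.4e-05 (adjusted p = 0.51 with an estimated correlation). Of 20 monocyte and macrophage genes 15 rose, 1 fell and 4 did not pass, the same over the list alone, with ITGAM and the receptor MRC1 (3.76) first, at 0.00085 (adjusted p = 0.25 with an estimated correlation). Of 3279 tested genes under 1 CPM in the scramble ASO libraries with no expressed neighbour upstream, 52.7% rose at least 2-fold. The low-count filter keeps genes nearly absent in these libraries only where the POLR3G ASO libraries hold counts. Part of this share was therefore fixed in advance. Of the 35 ATF4 and integrated stress response genes 21 fell, 11 rose and 3 did not pass, unchanged over the list alone, PCK2 (-1.54) lower and PPP1R15A (1.09) higher, at 0.015 (adjusted p = 0.41 with an estimated correlation). In all, 14957 of 19586 genes passed, 7537 higher and 7420 lower, against 9437 and 5076 by library size only, where the median of all genes lay at 0.12. With that scaling 24 cytosolic ribosomal proteins fell and 10 rose (median -0.01 in place of -0.14), and 32 oxidative phosphorylation genes fell and 11 rose (median -0.05 in place of -0.17).

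The siRNA and the ASO lower the same target, and their effects on other genes were compared directly. SCG3 stood at 23.2 CPM with POLR3G siRNA and 0.207 CPM in its control, but at 1.1 CPM with the ASO and 0.606 CPM in its control (difference of log2 changes 5.94, SE 0.22). UNC13A (4.48), RAB3C (4.33), CPLX2 (4.20), GPR158 (4.10) and LRATD1 (3.76) were the next largest differences towards the siRNA. In the other direction, PSG5 led, but it stood at 0.0103 and 0.0257 CPM in the siRNA experiment, so no fold is given. It was followed by INHBE, which fell from 11.6 to 0.801 CPM with siRNA and stood at 25.7 CPM with the ASO against 10.8 CPM (-5.11, SE 0.1), then MUC4 (-5.01), GADD45G (-4.58), B3GALT4 (-4.44) and ARHGAP30 (-4.35). Of 20063 genes, 14060 differed, 6961 towards the siRNA and 7099 towards the ASO, against 4276 and 10120 by library size only, where the median of all genes lay at -0.38. Across 16922 genes the effects correlated at Spearman 0.29, over genes that are not independent replicates. Of the genes tested in both, 2435 were higher and 4069 lower with each agent, where independent lists would share 2004 and 2944. Another 2407 were higher with the siRNA and lower with the ASO, and 1231 the other way, where independent lists would give 2806 and 2103.

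The POLR3GL siRNAs were each compared with control siRNA at 25 nM. With siE4 the adaptor DOK3 rose most, to 18.6 ± 2.2 CPM from 3.21 ± 0.46 CPM (log2 2.53, SE 0.12, n = 3 against 3). SAMD8 (2.42, SE 0.68) came next and lost significance without control siRNA 25 nM replicate 1 (2.13), then KCNJ14 (2.13), TMEFF1 (2.01), the lipid kinase PIP4K2A (1.99), and the hormone AMH (1.97). After the target, falls were largest in CHAC1 (-3.25, SE 0.082), the telomere protein CTC1 (-2.42), the G protein subunit GNB1 (-2.39), FBXO36 (-2.29), the nuclear receptor NR6A1 (-2.20), PSAT1 (-2.20) and TEF (-2.20). POLR3G was lower too (log2 -0.68, SE 0.069).

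Camera called 11 lists with siE4, 8 higher and 3 lower. Of the 35 ATF4 and integrated stress response genes 28 fell and 7 did not pass, the same adjusted over the list alone, led by CHAC1, the transporter SLC7A5 (-1.78), AARS1 (-1.34) and PSAT1, at an adjusted p of 2.4e-10 (adjusted p = 0.99 with an estimated correlation). Cytosolic ribosomal proteins rose in 62, fell in 2 and did not pass in 17 of 81 cases (65 and 2 adjusted over the list alone), among them RPL36 (-1.2) and RPL34 (0.71), at 7.1e-09 (adjusted p = 0.99 with an estimated correlation). Of 36 G2/M genes 27 rose, 2 fell and 7 did not pass, unchanged over the list alone, with BUB1 (0.52) and BIRC5 (0.57), at 2.6e-06 (adjusted p = 0.99 with an estimated correlation). All 13 mitochondrially encoded mRNAs rose, also over the list alone, such as MT-ND3 (0.77), at 0.0026 (adjusted p = 0.99 with an estimated correlation), but 7 rose by library size only. The mitochondrial share was 4.69, 2.59 and 3.61% in the control libraries and 5.85, 5.19 and 5.35% with siE4. In all, 9905 of 17282 genes passed, 4678 higher and 5227 lower, against 3470 and 6573 by library size only, where the median of all genes lay at -0.12.

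With siE6 NTN1 was among the genes that rose, to 43.7 ± 1.8 CPM from 8.22 ± 0.2 CPM (log2 2.41, SE 0.05, n = 3 against 3). Others were the histone gene H2AC25 (2.22), NSMF (2.21), the DNA methyltransferase DNMT3B (2.08), SLC36A1 (2.02), C10orf95 (2.01) and the coactivator WWTR1 (1.97). After the target, KRCC1 (-3.16, SE 0.074), JDP2 (-2.83), UBE2QL1 (-2.83), CHAC1 (-2.71), ETNPPL (-2.67), the neurofilament NEFM (-2.65) and G0S2 (-2.61) fell most. POLR3G was lower by less than with siE4 (log2 -0.27, SE 0.068).

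Camera called 18 lists with siE6, 16 higher and 2 lower. Of 81 cytosolic ribosomal proteins 67 rose, 1 fell and 13 did not pass, the same adjusted over the list alone, with RPL34 (0.79) higher and RPS27 (-0.83) lower, at an adjusted p of 2.3e-07 (adjusted p = 0.76 with an estimated correlation). The ATF4 and integrated stress response genes fell in 24, rose in 5 and did not pass in 6 of 35 cases (25 and 5 adjusted over the list alone), led by CHAC1, NIBAN1 (-1.61), JDP2 and SLC7A11 (-1.69), at 0.0001 (adjusted p = 0.76 with an estimated correlation). Of 20 heat shock genes 14 rose, 2 fell and 4 did not pass, unchanged over the list alone, HSPA1B (1.69) and HSP90AA1 (1.10) first, at 0.0024 (adjusted p = 0.76 with an estimated correlation). Genes of cholesterol synthesis rose in 15, fell in 3 and did not pass in 5 of 23 cases, alike over the list alone, such as LSS (0.78), at 0.0025 (adjusted p = 0.76 with an estimated correlation). Of 23 p53 targets 16 rose, 4 fell and 3 did not pass, the same over the list alone, among them TP53INP1 (1.64) and the cell cycle inhibitor CDKN1A (1.38), at 0.0025 (adjusted p = 0.76 with an estimated correlation). NF-kB and inflammatory genes rose in 14, fell in 4 and did not pass in 4 of 22 cases, also over the list alone, led by TNFAIP3 (1.2), at 0.0072 (adjusted p = 0.76 with an estimated correlation). Zinc finger genes rose in 198 and fell in 100 of 453 cases, unchanged over the list alone, at 0.04 (adjusted p = 0.76 with an estimated correlation, 0.093 without control siRNA 25 nM replicate 2), but 134 rose and 138 fell by library size only. In all, 11311 of 17282 genes passed, 5578 higher and 5733 lower, against 4233 and 6986 by library size only, where the median of all genes lay at -0.11.

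With siE8 the largest rise was in AP3B2 of the neuronal adaptor complex. It stood at 5.67 ± 1.3 CPM against 0.507 ± 0.15 CPM (log2 3.48, SE 0.2, n = 3 against 3), then came SYP (3.17, SE 0.053), KCNC1 (3.05), SAMD8 (2.54), the presynaptic scaffold BSN (2.52), UNC13A (2.49), BICDL1 (2.43) and RAB39A (2.43). After the target, REEP3 (-2.98, SE 0.06), NCEH1 (-2.63), the lipid enzyme ACSL4 (-2.60), the netrin receptor UNC5C (-2.58), NR6A1 (-2.47), GPC6 (-2.44) and GPM6A (-2.44) fell most. POLR3G was lower (log2 -0.83, SE 0.069) and POLR3A higher (0.23, SE 0.04).

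Camera called 9 lists with siE8, 8 higher and 1 lower. Of 24 genes of extracellular matrix and adhesion 21 fell, 1 rose and 2 did not pass (22 and 1 adjusted over the list alone), among them the integrin ITGB1 (-1.15) and the collagens COL3A1 (-2.10) and COL5A1 (-1.73), at an adjusted p of 2e-07 (adjusted p = 0.94 with an estimated correlation). G1/S genes rose in 26, fell in 2 and did not pass in 7 of 35 cases (27 and 3 adjusted over the list alone), led by E2F2 (1.67) and E2F1 (0.97), at 1e-05 (adjusted p = 0.94 with an estimated correlation). Of 56 ribosome biogenesis factors 34 rose, 5 fell and 17 did not pass (34 and 6 adjusted over the list alone), with DDX10 (1.2) first, at 0.00019 (adjusted p = 0.94 with an estimated correlation). Pol III subunits rose in 15 and fell in 3 of 18 cases, the same over the list alone, with POLR3F (0.93) and POLR3D (0.65) next after the target, at 0.02 (adjusted p = 0.94 with an estimated correlation). The ATF4 and integrated stress response genes were not called, with 13 that rose, 10 that fell and 12 that did not pass (13 and 11 adjusted over the list alone). In all, 10317 of 17282 genes passed, 5220 higher and 5097 lower, against 4921 and 5387 by library size only.

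The 3 POLR3GL siRNAs shared 2735 genes called in 1 direction, 1385 higher and 1350 lower. Independent lists of these sizes would share 456 and 511. In 10 simulations with no effects and only the control libraries shared, 0 genes were called with all 3, which does not measure how the controls act beside real effects, so part of the excess may come from them. Log2 changes correlated at 0.345 (siE4 and siE6), 0.331 (siE4 and siE8) and 0.367 (siE6 and siE8). The simulated means of 0.504, 0.499 and 0.497 come from the shared control libraries alone, so they are no yardstick for real effects. Covariances were 0.157, 0.139 and 0.185, against simulated means of 0.046, 0.046 and 0.047. By library size only the shared genes divided into 974 higher and 1889 lower. Effects differed between siRNAs for most genes: 11528 of 17282 between siE4 and siE6, 11204 between siE4 and siE8 and 11493 between siE6 and siE8. Between siE4 and siE6, ZNF536 (3.27, SE 0.52), the adhesion molecule CADM2 (3.25), UNC5C (2.93) and NIPAL2 (2.87) were highest towards siE4. Between siE4 and siE8, REEP3 (3.59, SE 0.061), ZCCHC12 (3.53) and DOK3 (3.36) were highest towards siE4. Between siE6 and siE8, KRCC1 (-3.76, SE 0.074), the axonal enzyme NMNAT2 (-3.59) and AP3B2 (-3.24) were highest towards siE8.

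With MAF1 overexpression few messenger RNAs beyond its own passed the threshold. The smooth muscle actin ACTA2 rose from 6.36 ± 0.07 to 9.07 ± 0.58 CPM (log2 0.51, SE 0.059, n = 3 against 3), a call lost without eGFP OE replicate 2 (0.52). ALDH1L1, a folate enzyme, was lowest at -0.48 (SE 0.075) and was lost without any single eGFP OE library (-0.52, -0.44 and -0.48) and without MAF1 OE replicate 2 (-0.44). POLR3A (-0.03, SE 0.061), POLR3G (0.13, SE 0.071) and POLR3GL (0.08, SE 0.057) did not pass. Of 34 ATF4 and integrated stress response genes 4 rose and 30 did not pass (14 rose adjusted over the list alone), led by PSAT1 (0.24, lost without eGFP OE replicate 2 at 0.24), at an adjusted p of 1.1e-07 (adjusted p = 0.52 with an estimated correlation). Of 56 ribosome biogenesis factors 1 fell and 55 did not pass (15 fell and 1 rose adjusted over the list alone), at 2.9e-13 and a median of -0.06 (adjusted p = 0.52 with an estimated correlation). Camera called 12 lists, 3 higher and 9 lower. In all, 40 of 17253 genes passed in edgeR, 21 higher and 19 lower, against 9 and 12 by library size only, where 1 ATF4 and integrated stress response gene rose. In the first fit 2127 had an unadjusted p under 0.05. With no change, simulations gave such a p to 4.38% to 4.8% of genes with gene-specific spreads and 4.69% to 5.26% with a trended spread. Both are smaller shares than 2127 of 17253, so changes too small to pass may be present. The simulated genes vary independently, however, so variation that genes of a library share may also raise the real share. DESeq2 called 134 and limma voom 15. The count was 12, 4 and 12 without eGFP OE replicate 1, 2 and 3, and 19, 8 and 199 without MAF1 OE replicate 1, 2 and 3.

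In THP-1 cells, 4 h of ML60218 raised PDK4, a kinase that restrains glucose oxidation, most. It stood at 113 ± 14 CPM against 16.8 ± 0.41 CPM in DMSO (log2 2.75, SE 0.081, n = 3 against 3). The lipid droplet protein PLIN2 (2.60, SE 0.14), the EGR corepressor NAB2 (1.84), heme oxygenase HMOX1 (1.71), THBS1 (1.54) and ZNF366 (1.48) followed. SERPINB2, a plasminogen activator inhibitor, fell most, from 86.3 ± 6.6 to 30.1 ± 7.2 CPM (log2 -1.52, SE 0.2). MAP2K6 (-1.03), TRIM66 (-0.99), POU4F2 (-0.85), KCNJ2 (-0.83), DEPTOR (-0.82), ENPP2 (-0.82) and B3GNT7 (-0.79) came next. POLR3A (0.01, SE 0.055) and MAF1 (0.00, SE 0.032) did not pass, and POLR3GL was slightly lower (-0.16, SE 0.035).

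Camera called 16 lists with ML60218 in THP-1 cells, 11 higher and 5 lower. Of 34 ATF4 and integrated stress response genes 26 rose and 8 did not pass (29 rose adjusted over the list alone), led by SLC7A5 (0.85), ATF5 (0.37), SLC7A1 (0.26) and STC2 (1.17), at an adjusted p of 8.9e-18 (adjusted p = 0.34 with an estimated correlation). Immediate early genes rose in 27, fell in 2 and did not pass in 6 of 35 cases (29 and 3 adjusted over the list alone), with NR4A1 (1.32) and DUSP4 (0.76), at 4.6e-14 (adjusted p = 0.26 with an estimated correlation). Of 28 NF-kB and inflammatory genes 17 rose, 1 fell and 10 did not pass (18 and 1 adjusted over the list alone), led by RELB (1.13), NFKBIA (0.56) and TNF (1.12), at 1.9e-12 (adjusted p = 0.26 with an estimated correlation). G1/S genes fell in 22 and did not pass in 13 of 35 cases (26 fell adjusted over the list alone), such as DTL (-0.24), at 1.7e-08 (adjusted p = 0.41 with an estimated correlation). Of 23 cholesterol synthesis genes 15 rose, 1 fell and 7 did not pass (16 and 2 adjusted over the list alone), CYP51A1 (0.46) among them, at 4.1e-08 (adjusted p = 0.41 with an estimated correlation). NRF2 targets rose in 11 and did not pass in 12 of 23 cases, the same over the list alone, with ME1 (1.01) and SRXN1 (0.46), at 2.4e-07 (adjusted p = 0.26 with an estimated correlation). Of 19 chaperone genes of the unfolded protein response 11 fell, 2 rose and 6 did not pass (13 and 2 adjusted over the list alone), HSPA5 (-0.39) first, at 4.8e-05 (adjusted p = 0.34 with an estimated correlation). In all, 3634 of 17102 genes passed, 1826 higher and 1808 lower, and 127 rose and 27 fell at least 2-fold. By library size only 1680 were higher and 2360 lower, and 1606 and 1954 without THP-1 DMSO replicate 3.

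Cycloheximide alone raised BIRC3, an inhibitor of apoptosis, most. It stood at 59.5 ± 6.3 CPM against 1.93 ± 0.23 CPM (log2 4.94, SE 0.11, n = 3 against 3). The adhesion molecule ICAM1 (4.57, SE 0.082), THBS1 (4.03), RELB (3.11), BCL3 (3.10), TNFAIP3 (3.06), TYW1B (2.93) and NFKBIE (2.91) followed. Cyclin E2, CCNE2, fell from 63.2 ± 1.9 to 4.22 ± 0.25 CPM (log2 -3.91, SE 0.065). Of 81 cytosolic ribosomal proteins 80 fell and 1 did not pass, the same adjusted over the list alone, by around the list's median of -0.57, RPL15 (-0.94) first, at an adjusted p of 7.8e-23 (adjusted p = 0.25 with an estimated correlation). G1/S genes fell in 32, rose in 2 and did not pass in 1 of 35 cases, alike over the list alone, led by CCNE2, FEN1 (-1.90) and E2F1 (-1.74), at 1.4e-09 (adjusted p = 0.22 with an estimated correlation). Of 26 MYC targets 24 fell, 1 rose and 1 did not pass, unchanged over the list alone, TFRC (-1.34) first, at 1.4e-08 (adjusted p = 0.25 with an estimated correlation). Poly(A) RNA of replication-dependent histones rose in 51 and did not pass in 6 of 57 cases (52 rose adjusted over the list alone), such as H2AC6 (1.69), at 9.5e-08 (adjusted p = 0.19 with an estimated correlation). All 19 chaperone genes of the unfolded protein response fell, also over the list alone, SEL1L (-0.78) and CALR (-0.91) first, at 1.8e-07 (adjusted p = 0.19 with an estimated correlation). Of 28 NF-kB and inflammatory genes 24 rose, 1 fell and 3 did not pass, the same over the list alone, at 2.6e-07 (adjusted p = 0.22 with an estimated correlation). Heat shock genes fell in 16, rose in 2 and did not pass in 1 of 19 cases, alike over the list alone, led by HSPA8 (-2.61), at 1.5e-06 (adjusted p = 0.19 with an estimated correlation). Of 10 transcripts and factors of nonsense-mediated decay 9 rose and 1 did not pass, also over the list alone, with GADD45B (2.39) and UPF2 (1.27), at 0.00024 (adjusted p = 0.1 with an estimated correlation). Camera called 21 lists, 8 higher and 13 lower, and 11638 of 17102 genes passed, 5828 higher and 5810 lower. By library size only the split was 7236 and 4379, and the median of all genes lay at 0.12.

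Added to CHX, ML60218 raised NGFR, a neurotrophin receptor, most. It stood at 14.4 ± 8.3 CPM against 1.57 ± 0.27 CPM with CHX alone (log2 3.19, SE 0.45, n = 3 against 3). The transcription factors EGR3 (3.17, SE 0.17) and FOSB (2.85, SE 0.12) were next, then RNF150 (2.25), NR4A3 (2.19), PDK4 (2.10), CAPN5 (1.74) and SLC16A6 (1.66). GPR82 (-1.08, SE 0.19), MAP2K6 (-1.08, SE 0.073), ENPP2 (-1.01) and IRAG1 (-0.85) fell most. Of 23 cholesterol synthesis genes 20 rose and 3 did not pass (21 rose adjusted over the list alone), led by STARD4 (0.73), SQLE (1.02) and SC5D (0.54), at an adjusted p of 2e-23 (adjusted p = 0.26 with an estimated correlation). Immediate early genes rose in 23, fell in 1 and did not pass in 11 of 35 cases, the same over the list alone, NR4A3, NR4A1 (1.59) and FOSB first, at 3.1e-13 (adjusted p = 0.26 with an estimated correlation). Of 28 NF-kB and inflammatory genes 13 rose, 1 fell and 14 did not pass (19 and 1 adjusted over the list alone), TNF (0.97) first, at 1e-06 (adjusted p = 0.6 with an estimated correlation). Interferon response genes fell in 14, rose in 2 and did not pass in 23 of 39 cases (16 and 2 adjusted over the list alone), such as OAS1 (-0.43), at 0.00024 (adjusted p = 0.6 with an estimated correlation). Of 34 ATF4 and integrated stress response genes 11 rose and 23 did not pass, unchanged over the list alone, SLC7A1 (0.35) and ATF3 (1.2) first, at 0.0057 (adjusted p = 0.68 with an estimated correlation). Camera called 17 lists, 14 higher and 3 lower, and 3809 of 17102 genes passed, 1923 higher and 1886 lower, against 1394 and 2850 by library size only and 1730 and 1872 without THP-1 CHX replicate 2.

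The interaction asks whether the response to ML60218 differed with CHX present. FOSB stood at 0.831 CPM in DMSO and 1.32 CPM with ML60218, but at 2.18 CPM with CHX and 15.8 CPM with both (difference of log2 changes 2.19, SE 0.21). In the other direction, PLIN2 rose from 54.1 to 328 CPM without CHX and from 142 to 314 CPM with it (-1.46, SE 0.19). CLIP2 stood at 20.9 and 44.5 CPM without CHX and at 14.3 and 11.3 CPM with it (-1.43, SE 0.1), and ZNF366 at 13 and 36.3 CPM without CHX and 9.07 and 9.93 CPM with it (-1.35, SE 0.18). Of 23 cholesterol synthesis genes 15 differed towards a larger rise with CHX, 1 the other way and 7 did not pass (17 and 1 adjusted over the list alone), at an adjusted p of 8.1e-14 (adjusted p = 0.37 with an estimated correlation). Of 34 ATF4 and integrated stress response genes 16 differed towards a smaller response with CHX, 1 towards a larger and 17 did not pass (17 and 1 adjusted over the list alone), at 5.4e-08 (adjusted p = 0.59 with an estimated correlation). Of 23 NRF2 targets 9 differed towards a smaller response and 14 did not pass (11 adjusted over the list alone), at 1.5e-06 (adjusted p = 0.33 with an estimated correlation). Camera called 19 lists, and 1606 of 17102 genes passed, 711 higher and 895 lower, against 615 and 1125 by library size only and 860 and 754 without THP-1 DMSO replicate 3.

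The ML60218 responses of the cell lines were also compared, although cell line and lane type differ together and the labels give no treatment time for HEK293T cells. The leading positive differences, SH3RF3, LHX1, HAND1 and IL13RA2, rest on THP-1 DMSO libraries that were all at 0, with at most 0.0366 CPM after ML60218, so no fold is given. The calls of SH3RF3, HAND1 and IL13RA2 were lost without THP-1 ML60218 replicate 1. TMEFF1 led the negative ones with all THP-1 ML60218 libraries at 0 and 0.176 CPM in DMSO, followed by GPR18, which stood at 0.00802 and 0.041 CPM in HEK293T, so no fold is given here either. Next were H4C15 (difference of log2 changes -2.37, SE 0.35) and H4C14 (-2.30, SE 0.49). H4C15 stood at 10.2 CPM in HEK293T DMSO and 36.4 ± 15 CPM with ML60218, against 16.3 and 11.3 CPM in THP-1. Of 18448 genes 5750 differed, 3218 towards a higher response in THP-1 and 2532 towards HEK293T, against 2038 and 4087 by library size only. Across 15551 genes the responses correlated at Spearman -0.01.

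Genes called in 1 direction in at least 5 of 7 experiments numbered 273, 99 higher and 174 lower. Independent lists over all 20763 genes tested in any experiment would give 22 and 26. That expectation counts untested genes as not called and treats all genes as equally easy to call, so it may be too low. It also treats the experiments as unrelated. A control siRNA seed, described below as a possibility, may add to the genes and correlations that siRNA experiments share. The minimum of 5 was set after the separate fits had been seen and before the overlap was counted. No gene was called alike in all 7, in which MAF1 called 40. Higher in 6 experiments were the pseudokinase gene TRIB1, QRSL1, IRF2BP2 and BRAF, with TRIB1 at log2 2.78 with POLR3G siRNA, 0.34 with POLR3A siRNA and 0.69 with ML60218 in THP-1. Lower in 6 were 13 genes, in order first the zinc transporter SLC39A10, the reticulon RTN3, BTN3A2, ENDOD1, the caveolin CAV1 and the tubulin TUBB, with SLC39A10 at -1.63 with POLR3A siRNA and -0.39 with POLR3G siRNA. Effects of POLR3A siRNA correlated across genes with those of POLR3G siRNA at 0.2, the ASO at 0.21 and the POLR3GL siRNAs at 0.3, and those of the POLR3GL siRNAs with POLR3G siRNA at 0.38 and the ASO at 0.23. ML60218 in HEK293T correlated with POLR3G siRNA at -0.24, the POLR3GL siRNAs at -0.22, POLR3A siRNA at -0.01 and the ASO at 0.02. Only 2 genes passed in 5 experiments when a change of at least 1.5-fold was also required.

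**Figure D3:**
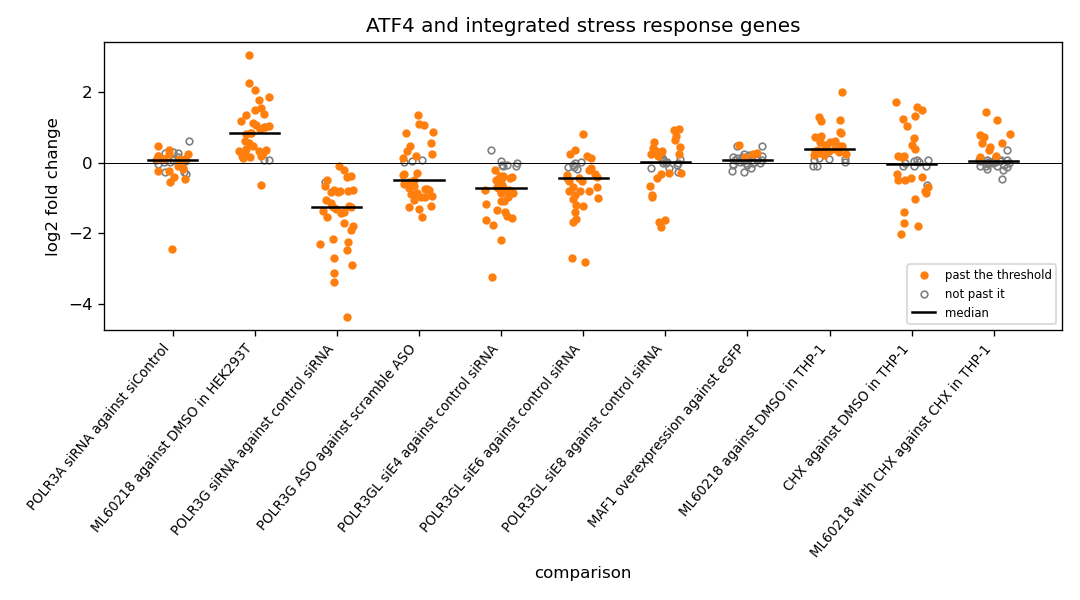
Log2 fold changes of the ATF4 and integrated stress response genes in each comparison. Each point is a gene, orange where it passed the threshold and open where it did not, and lines are medians. The median lies at 0.84 with ML60218 in HEK293T and at -1.26 with POLR3G siRNA. Each change is against the comparison's own control, and levels in the controls may differ, so medians do not compare levels between experiments.

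All 161 camera calls across the 11 comparisons and the 19 of the interaction were lost when the correlation between genes was estimated, the lowest adjusted p then being 0.081. Of the 161, 138 kept the call and 23 lost it by fry, which asks whether a list moved at all, not more than other genes. Correlation between genes is not the only possible reason for the loss. In the simulation of POLR3A siRNA with gene-specific spreads, genes varied independently. A moved list still went from a camera p of 8.4e-23 to 0.00036 with an estimated correlation of -0.01. The lists of Pol III transcription factors and regulators, apoptosis regulators and pluripotency genes were called in no comparison by camera. For the Pol III factors and regulators the adjusted p was lowest with ML60218 in HEK293T at 0.087, where 3 of 20 rose and 8 fell (4 and 9 adjusted over the list alone).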

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

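The 6 results here are differences between effects that were planned, and of their tests only the redrawing of the splits at 100 instead of 30 was chosen after a result was seen. The response to ML60218 differed with CHX present for 1606 genes, by a test of the interaction itself. Of 100 splits drawn from the 12 THP-1 libraries, 1 gave as many, the real one, and the highest other gave 992. Other splits mix treated and control libraries, which widens the spread within their groups and lowers their counts, so they do not exclude chance. Each set of 100 here is a random part of all possible splits. A split that kept both arms but reversed 1 would test the sum of the effects and might give as many. The share therefore depends on the draw. The effects of POLR3G siRNA and the POLR3G ASO differed for 14060 genes, where again 1 of 100 splits gave as many and the highest other gave 8049. The ML60218 responses of THP-1 and HEK293T cells differed for 5750 genes, with 1 of 100 splits as large and 4224 in the highest other. The high counts of other splits came from the 20 splits in each set that kept a real arm together, and without those the highest were 1, 2 and 2 genes. That comparison of cell lines confounds cell line and lane type, and the treatment time of HEK293T cells is not given, so what the difference belongs to cannot be told apart. Among the POLR3GL siRNAs, 11528 genes differed between siE4 and siE6, 11204 between siE4 and siE8 and 11493 between siE6 and siE8, and the highest other split gave 1 gene in each.

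Comparisons of 3 against 3 libraries have 10 splits, which are too few for a share under 0.05, and this holds for the 3 differences between POLR3GL siRNAs too. In each of them 1 split, the real one, gave as many genes. The real count and the highest other were 10604 and 1 for POLR3A siRNA, 7582 and 0 for ML60218 in HEK293T, 13231 and 0 for POLR3G siRNA, 14957 and 1 for the ASO, and 40 and 10 for MAF1. They were 9905 and 1 for siE4, 11311 and 0 for siE6, and 10317 and 1 for siE8. In THP-1 they were 3634 and 1 for ML60218, 11638 and 0 for CHX, and 3809 and 2 for ML60218 with CHX.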

How the results depend on the processing

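The transcript length offset, protein-coding genes only for named genes, and library size only and the replicate block for the overlap counts were chosen after seeing the data, and the other alternatives were fixed beforehand. The 7 targeted genes kept their direction and call in all 101 alternatives. Of 288 alternative counts, 270 stayed within 1.5 times the reported one. MAF1, with 40 genes, moved to 21 by library size only, 222 with no filter, 134 with DESeq2, 15 with limma voom, 71 with the replicate block, 9 with protein-coding genes only and 5 with the length offset. Without each library in turn its count ran from 4 (without eGFP OE replicate 2) to 199 (without MAF1 OE replicate 3). With the length offset, ML60218 with CHX gave 2484 genes, the interaction 970 and the overlap of several experiments 170 in place of 273. A change of at least 1.5-fold left 508 of the genes shared by the POLR3GL siRNAs (201 higher, 307 lower) and 2 in several experiments. With the POLR3G ASO, KMT2D turned to 0.11 and SOD2 to -0.12 under the length offset, and POLR3A to 0.02 by library size only. For these changes the cause was not tested. Among 23553 alternative values of named genes, 23131 kept direction and call, 414 lost the call, 5 gained it and 3 reversed. Of 1771 alternative tests of called lists, 1527 kept the call, 244 lost it and 0 reversed. The replicate block gave 3880 genes for ML60218 with CHX and 1685 for the interaction. Splitting the controls so that no lists share one was not run, since 3 libraries leave a part with 1. In simulations of MAF1 with gene-specific spreads, 37 of 50 genes changed by 1.2-fold and 45 by 1.5-fold were recovered, and with no change 1 to 9 genes were called.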

Other observations

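The gene lists here were fixed beforehand, while the tests of the 3 patterns after them were chosen once the patterns were seen, with predictions written before each was run, except for the 7-mer taken from POLR3A siRNA. Some gene lists tied to transfer RNAs, the main products of Pol III, and to Pol I are described here. Of 45 genes of tRNA processing and modification, 30 rose, 13 fell and 2 did not pass with POLR3G siRNA, the same adjusted over the list alone, led by LARP4 (1.19), RTCB (1.32), QTRT2 (1.08) and RPP14 (1.04), at a camera adjusted p of 0.0062 (adjusted p = 0.5 with an estimated correlation). With siE6 31 rose, 10 fell and 4 did not pass, alike over the list alone, RTCB (1.00) first, at 0.0057 (adjusted p = 0.76 with an estimated correlation). With siE8 29 rose, 8 fell and 8 did not pass, unchanged over the list alone, again with LARP4 (1.11) first, at 0.0009 (adjusted p = 0.94 with an estimated correlation). With MAF1 the list was called lower although no member passed, at 0.025 (adjusted p = 0.52 with an estimated correlation), a call lost without eGFP OE replicate 2 (0.11) and without MAF1 OE replicate 1 (0.072).

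Of 23 cytosolic aminoacyl-tRNA synthetases, 16 fell, 1 rose and 6 did not pass with the POLR3G ASO, alike over the list alone, QARS1 (-0.82) and AARS1 (-0.88) first, at 0.00038 (adjusted p = 0.39 with an estimated correlation), but 12 fell and 7 rose by library size only. With CHX in THP-1 cells 15 of them fell, 2 rose and 6 did not pass, also over the list alone, at 0.0026 (adjusted p = 0.4 with an estimated correlation), against 14 and 6 by library size only. With ML60218 in HEK293T cells 11 rose, 5 fell and 7 did not pass (11 and 6 adjusted over the list alone), at 0.046 (adjusted p = 0.73 with an estimated correlation), against 15 and 2 by library size only. That call was lost without DMSO replicate 1 (0.056), DMSO replicate 3 (0.072) or ML60218 replicate 2 (0.12). With ML60218 in THP-1 cells 8 rose and 15 did not pass (8 rose and 3 fell adjusted over the list alone), at 0.038 (adjusted p = 0.64 with an estimated correlation), lost without THP-1 DMSO replicate 3 (0.26) and by library size only (0.06). Subunits and factors of Pol I rose in 10 of 12 cases with POLR3G siRNA and 2 did not pass (11 adjusted over the list alone), such as POLR1F (0.94) and RRN3 (0.73), at 0.00095 (adjusted p = 0.5 with an estimated correlation). With the ASO 9 of them rose, 1 fell and 2 did not pass, the same over the list alone, TAF1D (0.42) first, at 0.016 (adjusted p = 0.3 with an estimated correlation). With MAF1 the Pol I list was called lower with no member past the threshold, at 0.0056 (adjusted p = 0.52 with an estimated correlation). With ML60218 added to CHX 4 rose and 8 did not pass, the same over the list alone, at 0.033 (adjusted p = 0.65 with an estimated correlation), lost without THP-1 CHX replicate 1 (0.052) and by library size only (0.088). In the interaction 3 differed towards a larger response with CHX and 9 did not pass (8 adjusted over the list alone), at 0.00043 (adjusted p = 0.37 with an estimated correlation).

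Low-count genes were higher in the POLR3G ASO libraries, where 3740 genes rose and 242 fell at least 2-fold. Depth is argued against, since after thinning to a single total the lowest ASO library still held 2374 more genes with at least 10 counts than the highest scramble library. Of 1190 low genes with an expressed neighbour upstream on the same strand 70.8% rose at least 2-fold, against 51.7% of 726 with such a neighbour on the other strand, a gap of 19.2 points (95% interval 14.7 to 23.6). That interval takes genes as independent. Genomic DNA would bring both strands alike, so the gap argues against it only for the added rise beside same-strand neighbours. A candidate explanation for this part is transcription running on from upstream genes. Much stays open, since 52.7% of 3279 low genes with neither neighbour rose as well, close to the 51.7%. For such an even rise genomic DNA is not argued against, and choosing genes by a low control level may raise that share. The low-count filter can add to all of these shares and to the 3740 rises. Through it, genes nearly absent in the control enter only by their counts in the ASO libraries. Whether lower POLR3G or the oligonucleotide itself is behind the pattern was not tested.

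Each POLR3GL siRNA lowered many genes beside its target, and loss of POLR3GL as the whole reason is argued against, since of the genes at least 2-fold lower only 34.5% with siE4, 28.4% with siE6 and 32.5% with siE8 were called lower with both others. Matches of siRNA seeds in 3' UTRs may account for part of them, since a different 7-mer stood out for each, AACGTGG for siE4 (z of -7.6), GAGGAAA for siE6 (-13.7) and GCTATCT for siE8 (-19.7), a smallest size of 7.6 against at most 4.5 with ML60218 or MAF1, 4.7 with CHX and 5.9 with the ASO. The same scan gave GGAGGGA (-15.3) with POLR3A siRNA and CCGCAGA (-8.3) with POLR3G siRNA, so the pattern is not particular to the POLR3GL siRNAs. A seed of a control siRNA may likewise add to rises, since genes with AGACGTA, the 7-mer highest with POLR3A siRNA (7.9), were higher with POLR3G siRNA (5.6) and siE4, siE6 and siE8 (7.8, 7.4 and 7.6), against -1.3 to 1.3 in the comparisons without siRNA. The sequences of the siRNAs were not used here, and the part of POLR3GL loss in the shared genes stays open.

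Genes known from synapses were among the largest rises, SYP with POLR3A siRNA and siE8 and UNC13A with POLR3G siRNA and siE8, although no list of such genes was tested. A candidate explanation is lower mRNA of REST, which represses neuronal genes, at a log2 change of -0.54 with POLR3A siRNA, -0.91 with POLR3G siRNA and -1.12 with siE8, against 0.09 with siE4 and -0.09 with siE6. REST also fell with the POLR3G ASO (-0.21), where UNC13A stood at 3.09 CPM against 3.15 CPM, SCG3 at 1.1 against 0.606 CPM and CPLX2 at 0.953 against 0.169 CPM, and with ML60218 in HEK293T (-0.17). Less Pol III activity stays open: of the 148 tested genes at least 2-fold higher with both POLR3A and POLR3G siRNA, 23 were called lower and 12 higher with ML60218 in HEK293T (exact binomial p = 0.09, two-sided). That set was not chosen by function, so its count does not address synaptic genes, and REST protein was not measured.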
